A study of Mus musculus with 4 samples.

How the data were processed

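Gene expression was measured in mitomycin C-inactivated CF1 mouse embryonic fibroblasts, the feeder layer used to grow human embryonic stem cells. Per the labels, cells were plated on gelatine at 55000 cells per square centimetre and kept for 24 h in basic human embryonic stem cell medium with 0, 4, 13 or 40 ng/ml of FGF2. From each RNA preparation 300 ng was amplified (6 h of in vitro transcription), labelled with Cy3 and hybridised to a one-colour Illumina bead array with 46116 probes. There were 6 arrays, made of 3 biological replicates of the untreated control and 1 array at each of the 3 doses. Whether arrays shared a slide or a hybridisation day is not given in the sources used here.

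Per the file headers, each array has a mean signal per probe, which is an intensity on a linear scale summarised with BeadStudio 1.0. These values are neither background-subtracted nor normalised between arrays. Per the file headers, each probe also has a detection score between 0 and 1, which ranks its signal among the negative controls of the same array. The authors also deposited a value table in the intensity unit. In it, each treated column is a straight-line function of that array's signal (Pearson r = 1 across probes), values with a score under 0.99 are blank, and the control column is the mean over the 3 replicates. The arrays were analysed from the signals, and the value table was used only as an alternative source of fold changes. The bead standard deviations were not analysed here. The precision is limited by the number of arrays.

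Background correction and normalisation used neqc in limma 3.58.1 with R 4.3.3. The mean and spread of the negative controls were inferred from the detection scores, an offset of 16 was added, and the signals were quantile-normalised between arrays and taken to log2. The detection scores show that each array has 1 very bright negative control, with a signal of at least 25610 on control replicate 1 and at least 28210 on the 13 ng/ml array. It sets the inferred standard deviation of the controls at 224 to 263, whereas 1 standard deviation above the control median corresponds to only 14.2 to 17.5 units of signal. This makes the changes of dim probes smaller than they would be otherwise, so log2 changes of genes near the detection limit are conservative. Normexp without control probes was therefore added as an alternative after the data had been seen. It was considered for the principal analysis once its counts were known, and was kept as an alternative because the method had been fixed beforehand. Probes were tested if their detection score was at least 0.99 on at least 3 of the 6 arrays, which left 11763 probes.

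The array files name probes by identifiers without gene symbols. In many identifiers a number follows a fixed prefix and 1 or 2 leading zeros, and this number was read as an NCBI gene number and matched to RefSeq annotation of the mouse assembly GRCm38.p6. This reading is an inference. It was checked in several ways. Of the numbers with 1 leading zero, 81.1% are mouse gene numbers, against 24.6% after shifting every number, and with 2 leading zeros the shares were 84.8% and 26.3%. Of the probes read as ribosomal protein genes, 56 of 56 with 1 leading zero were detected, against 5 of 9 when each number was shifted. With 2 leading zeros this check did not separate the reading from a shifted one (10 of 20 against 6 of 10). Of those read as olfactory, vomeronasal and taste receptors or defensins, 1 of 391 with 1 leading zero and 0 of 79 with 2 were detected. Across 300 genes with a detected probe of each kind, the log2 changes of the pair correlated at 0.81 (genes are not independent replicates), against at most 0.22 in 100 shuffles of the genes. A reading of clone names did no better than shuffled genes (0.50 against 0.51 across 25 genes) and was dropped. Together with 9 probes named by a RefSeq accession, 8131 genes were named, of which 3484 had a detected probe. Of 349 genes with more than 1 detected probe, 88 had 2 that passed the threshold, and 0 of these moved in opposite directions. Where a gene had several probes, the one with the highest mean signal stood for it. Genome positions of the probes were not analysed here.

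Tests were two-sided and fitted with lmFit and eBayes in limma, with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. The principal comparison set the 3 FGF2 arrays against the 3 control arrays, so that differences between doses count as spread. A slope per log2 of dose was fitted among the treated arrays, with separate intercepts for control and FGF2. Each dose was also set against the 3 controls, and there the single treated array is assumed to vary like the controls. A total of 27 gene lists were fixed before the data were examined, as were the comparisons and the first set of alternative settings. List members without a named probe were not measured here, which does not mean that they were not expressed. Lists with at least 5 detected genes were tested with camera in limma at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. The fry test in limma was run beside it, which asks whether a list's genes move on balance one way, without comparing them with the other genes.

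The genes named in the results were chosen by a rule fixed before the data were examined. It takes the 12 largest rises and the 12 largest falls among probes past the threshold whose 3 FGF2 arrays all lay on 1 side of the 3 controls. It also takes the 5 largest slopes each way, up to 4 detected members of each list with the smallest p, and Inhba, Tgfb1, Grem1 and Bmp4, which the study's publication is known to have followed. No probe could be read as any of these 4 genes, and they are not analysed here. Further members of lists are named as examples chosen after their values were seen. For a gene undetected on every array of 1 side, the fold was computed against the lowest detected signal of those arrays and is given as a lower bound.

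The alternative settings fixed beforehand were no further background correction, an offset of 50, scaling to the same median, no filter on dim probes, detection on all 6 arrays, a trended and robust prior, leaving out each array in turn, a slope on the dose itself, a rank trend over the 4 levels, an estimated correlation for the lists, the mean of all probes of a gene, and the authors' value table. Normexp with offsets of 50 and 16, lists restricted to probes with 1 leading zero, and a trended prior in camera, were added after the data had been seen. The fits were tested on simulated data with 50 probes changed at each size among 11763. For all doses against control, 96% of the probes raised by 1 log2 unit and 22% of those raised by 0.5 were recovered, with 15 false calls. Of the probes lowered by 1, 72% were recovered. In this simulation each changed probe moved alike at all 3 doses, and few probes changed. In the data the doses differed, which counts as spread, and 36.8% of probes passed. These recovery rates therefore do not carry over to the data. For the 40 ng/ml array alone, 30% and 6% of the probes raised by 1 and 0.5 and 12% of those lowered by 1 were recovered, with 0 false calls. For the slope test the simulated change was given per dose step. The slope test recovered 14% of the probes rising by 0.5 per step, 52% by 1 and only 34% by 2. It recovered 56% of those falling by 1 per step, with 3 false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.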

Results

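The series compared untreated with FGF2-treated inactivated fibroblasts, in the medium used for human embryonic stem cells, and asked how this feeder layer responds to the growth factor over a range of doses. The 6 arrays had similar depth, with a median signal of 102.5 to 113.6 over 46116 probes. Between 11195 probes (4 ng/ml) and 11698 probes (control replicate 3) were detected per array. After normalisation, 88.6% of the variance over the detected probes lay on the first principal component, where the controls scored -24.9 to -23.5 and the FGF2 arrays 13.6 (4 ng/ml), 29.5 (13 ng/ml) and 29.7 (40 ng/ml). Across probes, which are not independent replicates, log2 signals correlated at 0.995 to 0.997 between controls and at 0.998 between the 13 and 40 ng/ml arrays. The correlation was 0.945 to 0.972 between a control and an FGF2 array. Gene symbols throughout are inferred from the number in each probe's identifier. Inhba, Tgfb1, Grem1 and Bmp4, which the study's publication is known to have followed, could not be matched to a probe and are not analysed here.

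**Figure D1:**
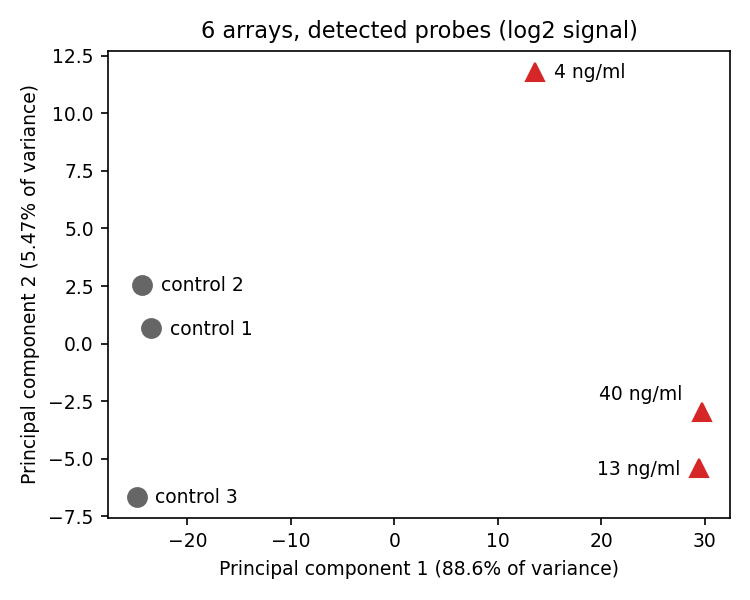
Scores of the 6 arrays on the first and second principal components of the log2 signals of detected probes (88.6% and 5.47% of the variance); grey circles are the 3 controls and red triangles the 3 FGF2 arrays. The controls lie between -24.9 and -23.5 on the first component, the 4 ng/ml array at 13.6, and the 13 and 40 ng/ml arrays at 29.5 and 29.7.

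The first comparison asked which genes changed with FGF2, taking the 3 doses together against the 3 controls. Among the named genes, the largest rise with neqc was that of Errfi1 (NCBI gene 74155), a feedback inhibitor of the EGF receptor. Errfi1 rose by 3.91 ± 0.33 on the log2 scale (SE of the fit, n = 3 per side throughout) or 15-fold. Gch1, the first enzyme of tetrahydrobiopterin synthesis, rose 11.9-fold (log2 3.58 ± 0.31). Without further background correction Errfi1 rose 9.83-fold and with normexp (offset 50) 9.69-fold. Ranks under alternative settings were sought only among the 101 genes picked by the naming rule, not among all genes with a symbol. Of these 101, Gch1 had the largest rise in both settings (log2 3.60 and 3.53). With normexp at an offset of 16, Chrna1 had the largest rise of the 101 (log2 3.83) and Ptx3 the largest fall (log2 -4.44). This value for Chrna1 is set against controls on which it was undetected, so its rank is uncertain. Spp1, which encodes osteopontin, rose 5.70-fold, with a log2 change of 2.50 at 4 ng/ml, 2.53 at 13 ng/ml and 2.50 at 40 ng/ml. Etv1, an ETS transcription factor of FGF signalling, rose 3.82-fold (log2 1.93 ± 0.15). Rasa1, a GTPase-activating protein for Ras, rose 4.33-fold, the cyclooxygenase Ptgs1 5.34-fold and Tmcc3 4.45-fold. With normexp (offset 50) the log2 changes of Rasa1 and Tmcc3 were smaller (1.66 and 1.69 in place of 2.115 and 2.15). That of Ptgs1 was 2.49 in place of 2.42. Socs2, a suppressor of cytokine signalling, rose 3.86-fold (log2 1.95 ± 0.43, adjusted p = 0.0197). Chrna1, a subunit of the muscle acetylcholine receptor, was undetected on all 3 controls and detected on all 3 FGF2 arrays, and rose at least 3.62-fold. Probes of members of multigene families also rose, namely Gzme (8.82-fold, a granzyme), Trbv31 (8.19-fold, a T cell receptor segment) and Hmga2-ps1 (10.2-fold, a pseudogene copy of Hmga2). Whether these 3 probes measured the named gene or a relative was not tested.

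Among the named genes, the largest fall with neqc was that of Ptn (NCBI gene 19242), the secreted growth factor pleiotrophin. Ptn fell by 4.70 ± 0.48 on the log2 scale (26.1-fold). Itga11, a collagen-binding integrin subunit, fell 19.8-fold (log2 -4.31 ± 0.16). Ptx3, a secreted pentraxin of innate immunity, fell 16.3-fold, and Ccdc80, a secreted matrix protein, fell 10.6-fold. Timp3, an inhibitor of matrix metalloproteases, fell 8.04-fold (log2 -3.01 ± 0.23). Tgfb3, a TGF-beta ligand, fell 5.39-fold, and the secreted Wnt antagonist Sfrp1 fell 5.35-fold. Col1a2, a chain of type I collagen, fell 4.94-fold, and the lysophosphatidic acid receptor Lpar4 5.98-fold. Pdgfrl fell 5.63-fold and Itgbl1 5.32-fold. Serpina3g, a serine protease inhibitor of a multigene family, fell 6.74-fold (log2 -2.75 ± 0.83), with log2 changes of -0.83 at 4 ng/ml, -3.36 at 13 ng/ml and -4.07 at 40 ng/ml. All other genes named in this and the preceding paragraph had adjusted p values between 9.16e-06 (Spp1) and 0.0197 (Socs2), and that of Serpina3g was 0.0491.

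In all, 4327 of 11763 probes passed the threshold in limma (36.8%), of which 2168 were higher and 2159 lower with FGF2. Of these, 473 differed more than 2-fold, 208 higher and 265 lower. Among the 3484 named genes, 663 rose and 652 fell. The unadjusted p was under 0.05 for 5530 of the 11763 probes. Many genes of any list would therefore pass when adjusted over the list alone, and such counts below are to be read against this share. The count was 2848 without control replicate 1 and 2598 without the 40 ng/ml array, and with scaling to the same median 37.9% of the called probes were higher in place of 50.1%. The call of Socs2 ended without any 1 of the 3 controls or the 13 ng/ml array (adjusted p up to 0.0661), and that of Serpina3g in each fit that left out an array except the one without the 4 ng/ml array (up to 0.138). Without the filter on dim probes neither passed (0.0651 and 0.152), and the call of Serpina3g also ended with scaling to the same median (0.0551), an offset of 50 (0.0514) and a trended robust prior (0.0635).

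**Figure D2:**
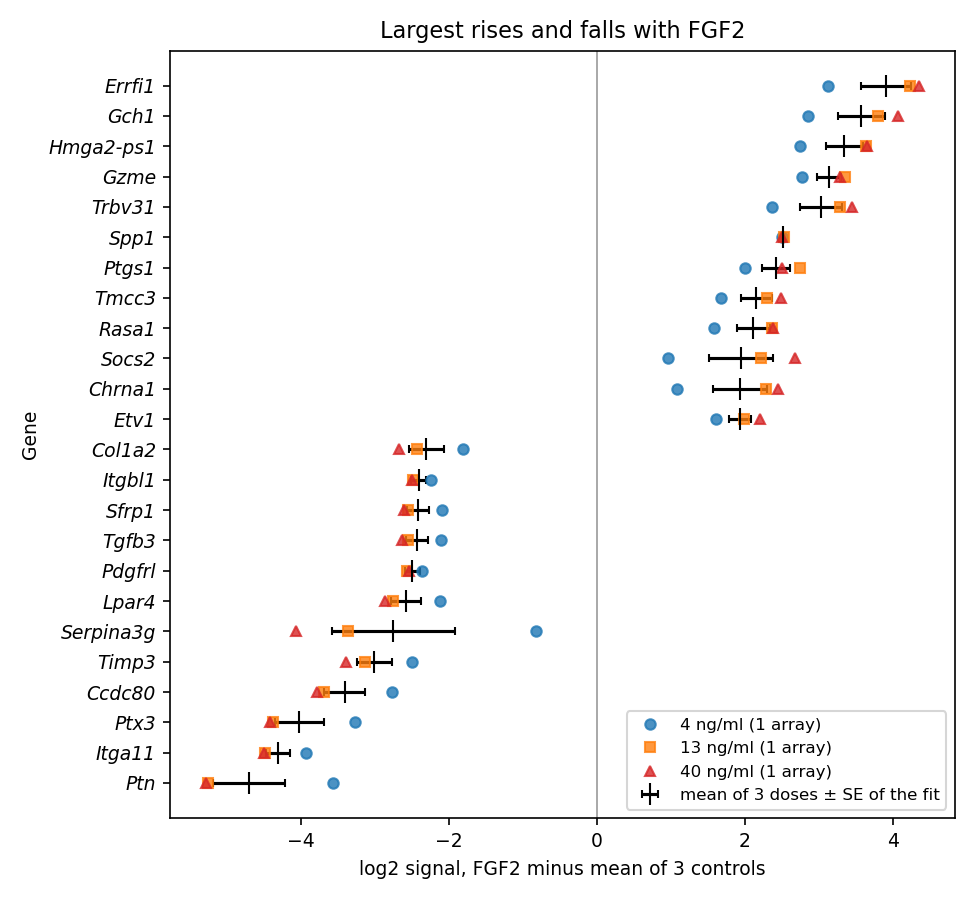
Log2 signal with FGF2 minus the mean of 3 controls for the 12 largest rises and 12 largest falls among named genes. Coloured points are the single arrays at 4, 13 and 40 ng/ml, and black ticks and bars the mean over the 3 doses with the SE of the fit. Errfi1 lies highest at 3.91 and Ptn lowest at -4.70, and the 3 points of Spp1 lie between 2.50 and 2.53.

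Most detected genes of the extracellular matrix and its turnover fell. Of the 45 members of the matrix list, 20 had a named probe. Of 17 detected matrix genes, 15 fell and 0 rose, and 17 passed when adjusted over the list alone (16 lower, and Dcn higher), with a median log2 change of -1.13. The fibrillar collagen Col1a1 fell 4.34-fold (log2 -2.12 ± 0.14), Thbs2 2.59-fold, Col6a1 1.90-fold and Thbs1 1.23-fold, while Dcn (log2 0.19, adjusted p = 0.0623) and Loxl1 (log2 -0.31, adjusted p = 0.0659) did not pass over all probes. The other chains that fell included Col8a1 (log2 -2.20), Col3a1 (log2 -1.47) and Col5a1 (log2 -1.13), along with elastin, Eln (log2 -1.07), and versican, Vcan (log2 -1.20). The list had an adjusted p = 8.1e-07 in camera, and an adjusted p = 0.463 with an estimated correlation. Of 8 matrix proteases and inhibitors, 7 fell and 7 passed when adjusted over the list alone, with a median of -0.90. They included the aggrecanases Adamts5 (4.04-fold) and Adamts4 (2.33-fold) and the metalloprotease Adam12 (1.49-fold), beside the inhibitor Timp3. Adamts5 was detected on 2 of the 3 FGF2 arrays and fell 6.58-fold with normexp. This list had an adjusted p = 0.000136, and an adjusted p = 0.463 with an estimated correlation. Of 5 TGF-beta target genes, 4 fell and 1 rose, and 5 passed when adjusted over the list alone. Those that fell were Col1a1, Col1a2, Ltbp2 (1.91-fold) and Acta2, and the matricellular gene Ccn1 rose 1.66-fold. The 4 that fell are also members of the matrix, antagonist or contractile lists, so the TGF-beta target list is not independent of those. This list had a median of -2.12 and an adjusted p = 0.0381, and an adjusted p = 0.47 with an estimated correlation; its call ended without control replicate 2 (adjusted p = 0.0662), without control replicate 3 (0.061) and with scaling to the same median (0.0757). Of 4 contractile genes, 2 fell, smooth muscle actin Acta2 and myosin light chain kinase Mylk. Acta2 fell 4.54-fold (log2 -2.18 with neqc and -1.74 with normexp). Mylk fell 3.21-fold with neqc and 5.49-fold with normexp, and was detected on 2 of the 3 FGF2 arrays. Cald1 (log2 -0.06, adjusted p = 0.162) and Palld (log2 -0.03, adjusted p = 0.786) did not pass.

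Ligands of the TGF-beta family that were detected fell or did not pass, and their antagonists went both ways. Of 4 ligands, Tgfb3 and Tgfb2 (3.19-fold, log2 -1.67 ± 0.07) fell, while Gdf15 (log2 -0.07, adjusted p = 0.344) and Gdf10 (log2 -0.02, adjusted p = 0.909) did not pass. Of 5 antagonists and latent binding proteins, Ltbp1 (2.28-fold) and Ltbp3 (1.39-fold) rose, and Ltbp2 (1.91-fold) and the BMP-binding protein Twsg1 (1.18-fold) fell. In this list 4 passed when adjusted over the list alone, the list's adjusted p was 0.972, and its test pointed down although its median (0.02) and mean (0.10) were above 0. These ligand and antagonist lists were drawn up with the knowledge that the study followed genes of this family, although none of the genes it is known to have followed is among the members measured here. The BMP target Id3, the only 1 of 15 members of its list with a named probe, fell 1.33-fold. The calls of Ltbp3, Twsg1 and Id3 each ended without the 13 ng/ml array, without the 40 ng/ml array and without either of 2 of the controls, with adjusted p values up to 0.0849, 0.0589 and 0.0636. That of Twsg1 also ended without further background correction (0.0672), with scaling to the same median (0.0561), with normexp at both offsets (0.0612 and 0.0813), without the filter (0.0563) and with a trended robust prior (0.063), that of Ltbp3 with scaling to the same median (0.0662) and without the filter (0.0804), and that of Id3 without the filter (0.0527).

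The few FGF signalling genes that were measured went both ways. Only 10 of the 27 FGF and ERK feedback and target genes had a named probe. Of the 7 detected, 4 rose and 2 fell, and 7 passed when adjusted over the list alone. Spry1, Spry2, Spry4, Dusp4, Dusp5, Dusp6, Etv4 and Etv5 were not among the 7, so the list covers little of this response. Errfi1, Etv1, the cyclin Ccnd1 (3.32-fold, log2 1.73 ± 0.18) and the ERK pathway inhibitor Spred1 (log2 0.23) rose. Cdc42ep3 (2.08-fold) and the ephrin receptor Epha4 (log2 -0.14) fell. Spred1 was detected on 1 of the 3 controls and Epha4 on 1 of the 3 FGF2 arrays. The list median was 0.23, and the list did not pass in camera (adjusted p = 0.187). Of 7 FGF ligands, receptors and co-receptors, the heparan sulfate proteoglycan Gpc1 rose 1.77-fold and Sdc2 fell 1.46-fold. Fgf13 was undetected with FGF2 and fell at least 1.02-fold, a call that ended in each of the 6 fits without 1 array (adjusted p up to 0.102). Sdc1 had a log2 change of -0.16 (adjusted p = 0.0684) and the receptor Fgfr1 of 0.00 (adjusted p = 0.988). Fgfr1 was detected on only 2 of the 3 controls and 2 of the 3 FGF2 arrays (mean log2 signal 7.26 on each side). At this detection limit a change could go unseen. In this list 4 genes passed when adjusted over the list alone, its median (-0.04) and mean (0.0047) differed in sign, and its adjusted p was 0.691.

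Most detected interferon response genes fell. Of 11 detected genes, 9 fell and 0 rose, and 10 passed when adjusted over the list alone, with a median of -0.56. The antigen presentation genes H2-K1 and B2m fell 2.53-fold and 1.47-fold, and the transcription factors Irf9 and Irf1 fell 2.36-fold and 1.34-fold. The antiviral genes Oas1a and Mx2 were detected on all 3 controls and on no FGF2 array, and fell at least 1.48-fold and 1.26-fold. With the 4 genes undetected with FGF2 set at their bounds, the list median was again -0.56. The list had an adjusted p = 0.000136, and an adjusted p = 0.463 with an estimated correlation. Control replicate 3 had a higher mean over this list (9.0) than control replicates 1 and 2 (8.63 and 8.57), against 7.95 to 8.04 on the FGF2 arrays.

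Among 14 detected genes of glycolysis and hypoxia, 8 rose, 0 fell and 6 did not pass, with a median of 0.35. When adjusted over the list alone 12 passed, 11 higher and 1 lower, the latter being Pfkl (log2 -0.21). The enzymes Eno1 (2.23-fold), Pkm (1.76-fold) and Gapdh (1.34-fold) and the oxygen sensor Egln3 (1.38-fold, and 2.27-fold with normexp) rose. The list had an adjusted p = 0.000564, and an adjusted p = 0.236 with an estimated correlation. Of 12 cholesterol synthesis genes, 5 rose and 1 fell, and 6 passed when adjusted over the list alone. Cyp51 rose 1.49-fold and Nsdhl 1.24-fold, while Tm7sf2 fell 1.08-fold. This list had a median of 0.18 and an adjusted p of 0.186. Of 5 genes of the unfolded protein and amino acid stress responses, Phgdh rose 1.08-fold, Vldlr fell 1.29-fold, and Cebpb (log2 0.45, adjusted p = 0.0774) and Xbp1 (log2 -0.23, adjusted p = 0.125) did not pass. Cebpb passed without further background correction (adjusted p = 0.0292), with normexp at both offsets (0.0272 and 0.036) and with a trended robust prior (0.0243). Here 2 passed when adjusted over the list alone, and the list's adjusted p was 0.972, with a median of 0.11 and a mean of 0.02 but a downward direction in fry. The calls of Tm7sf2, Nsdhl and Phgdh ended in 4, 5 and 5 of the 6 fits without 1 array, with adjusted p values up to 0.0666, 0.111 and 0.109.

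In the comparison of all doses with control, 3 genes of the G2 and M phases and 0 of the S phase passed. On the single array at 4 ng/ml, 3 S phase genes were higher, a count that depended on the settings and on the controls used. Of 7 S phase genes, 0 passed over all doses in limma, 1 had an unadjusted p under 0.05 (Pcna), and 0 passed when adjusted over the list alone. Pcna (log2 0.19, adjusted p = 0.0737), Fen1 (0.13, 0.148), Rrm2 (0.11, 0.357) and Uhrf1 (0.26, 0.428) had the smallest p values. At 4 ng/ml against control, Uhrf1 (log2 0.81, adjusted p = 0.00887), Rrm2 (0.30, 0.0259) and Pcna (0.31, 0.0459) were higher, and the list medians were 0.25 at 4 ng/ml, 0.0073 at 13 ng/ml and 0.0048 at 40 ng/ml. In the test of the slope per log2 of dose none of the 3 passed (Uhrf1 -0.24, adjusted p = 0.416; Rrm2 -0.09, 0.366; Pcna -0.07, 0.369). Of the 3, 0 passed at 4 ng/ml without control replicate 1 (smallest adjusted p = 0.0623), only Uhrf1 without control replicate 2 or with scaling to the same median, and Rrm2 not without control replicate 3 (0.0589). Without further background correction and with normexp at both offsets, Fen1 also passed at 4 ng/ml (adjusted p = 0.0303 to 0.0411). Of 7 genes of the G2 and M phases, the centromeric histone Cenpa rose 1.25-fold, and Nusap1 and Ccnb1 fell 1.18-fold and 1.07-fold, while the proliferation marker Mki67 did not pass (log2 -0.07, adjusted p = 0.14). With normexp, Pcna (adjusted p = 0.0411) and Mki67 (0.0491) passed, and the call of Cenpa ended with scaling to the same median (0.0858). In that list 3 passed when adjusted over the list alone. Of 7 p53 target genes, the cell cycle inhibitor Cdkn1a (1.20-fold), Zmat3 (1.31-fold) and Ccng1 (1.22-fold) fell and Pmaip1 rose 1.10-fold, and 4 passed when adjusted over the list alone. The adjusted p values of the 3 lists were 0.49, 0.795 and 0.32, and their medians 0.11, -0.03 and -0.07. The call of Nusap1 ended without the 40 ng/ml array (adjusted p = 0.0524), and those of Ccnb1 and Pmaip1 in 5 of the 6 fits without 1 array (up to 0.113 and 0.107).

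Secreted factors changed in both directions. Of 9 cytokines, chemokines and growth factors, 3 rose and 3 fell, and 8 passed when adjusted over the list alone. The chemokine Ccl2 rose 2.89-fold (log2 1.53 ± 0.11) and Pdgfa rose 1.59-fold, and the chemokine Cxcl14 fell 2.32-fold. Igf1 was undetected with FGF2 and fell at least 1.21-fold. The list's adjusted p was 0.972, with a median of 0.03 and a mean of 0.09 but a downward direction in fry. Of 6 genes of the IGF axis, 4 fell and 1 rose, and 5 passed when adjusted over the list alone. Igfbp3 fell 2.50-fold, Igfbp5 1.46-fold and Igfbp6 1.21-fold, and Igfbp4 rose 1.71-fold. This list had a median of -0.32 and an adjusted p of 0.186, and the calls of Igfbp5 and Igfbp6 each ended in 4 of the 6 fits without 1 array (adjusted p up to 0.0652 and 0.0539). Of 4 Wnt pathway genes, Sfrp1 and the receptor Fzd2 (1.22-fold) fell, Wnt5a rose 1.62-fold, and Nkd2 did not pass (log2 -0.05, adjusted p = 0.377).

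Many markers of other lineages had no named probe and were not measured, and the detected ones went both ways. A named probe existed for 11 of 16 neural, 5 of 14 endothelial and 5 of 15 epithelial markers. Of these, 4, 1 and 2 were detected. Of 19 adipogenic genes, 7 had a named probe and 4 were detected. Of 4 neural markers, Gap43 rose 3.19-fold (log2 1.67 with neqc and 1.26 with normexp). Nes, detected on 2 of the 3 controls, rose 1.83-fold with neqc and 3.59-fold with normexp. Ncam1 fell 1.21-fold, and Tubb3 did not pass (log2 -0.02, adjusted p = 0.675). Of 4 adipogenic genes, Fasn (1.28-fold) and Cebpa (1.08-fold) rose, and lipoprotein lipase, Lpl, and Scd2 (1.26-fold) fell. Lpl was detected on 1 of the 3 FGF2 arrays, and its log2 change was -0.43 with neqc and -1.23 with normexp. Of 2 skeletogenic genes, Spp1 rose and Mgp did not pass (log2 -0.29, adjusted p = 0.0621). The macrophage lysozyme Lyz2, the only 1 of 9 macrophage and leukocyte markers with a named probe that was detected, fell 1.32-fold. Among 2 epithelial markers, Krt18 was undetected on the controls and rose at least 1.12-fold, and Cldn4 did not pass (log2 0.00, adjusted p = 0.988). The endothelial marker Egfl7 was undetected on the controls and rose at least 1.03-fold, and Chrna1 was the only 1 of 19 muscle markers with a named probe. Of 4 erythroid markers with a named probe, 0 were detected. The calls of Fasn, Cebpa, Scd2 and Egfl7 ended in 4, 4, 5 and 4 of the 6 fits without 1 array, with adjusted p values up to 0.1, 0.0715, 0.0959 and 0.111.

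Of the 27 lists, 15 had at least 5 detected genes and were tested, and 5 passed in camera, 1 up and 4 down. With the correlation estimated from the data 0 of the 15 passed, where the smallest adjusted p was 0.236, whereas fry called 9. Fry does not compare a list with the other genes, and 37.7% of all named genes were called. Its calls therefore do not show that a list stands out. Normexp without control probes, which compresses dim signals less, moved the median of the interferon list to -1.49, that of the FGF and ERK list to 0.92 and that of the IGF list to -0.54. The medians of the matrix and TGF-beta target lists became smaller in size, at -1.01 and -1.74. Calls of other named list members also depended on settings. Those of Igfbp5 (adjusted p = 0.0671), Pmaip1 (0.0629), Nsdhl (0.123), Scd2 (0.095) and Fasn (0.108) ended without the filter on dim probes, and that of Ccnb1 with detection on all 6 arrays (0.0505). Those of Pmaip1 (0.107), Phgdh (0.16), Cebpa (0.106) and Egfl7 (0.0664) ended with scaling to the same median, under which Sdc1 (0.0488) and Mgp (0.0481) passed. Cebpb passed without control replicate 3 (0.00463), Xbp1, Mki67 and Mgp without the 4 ng/ml array (0.00819, 0.0463 and 0.0365), and Pcna and Mgp without the 40 ng/ml array (0.0445 and 0.0325).

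**Figure D3:**
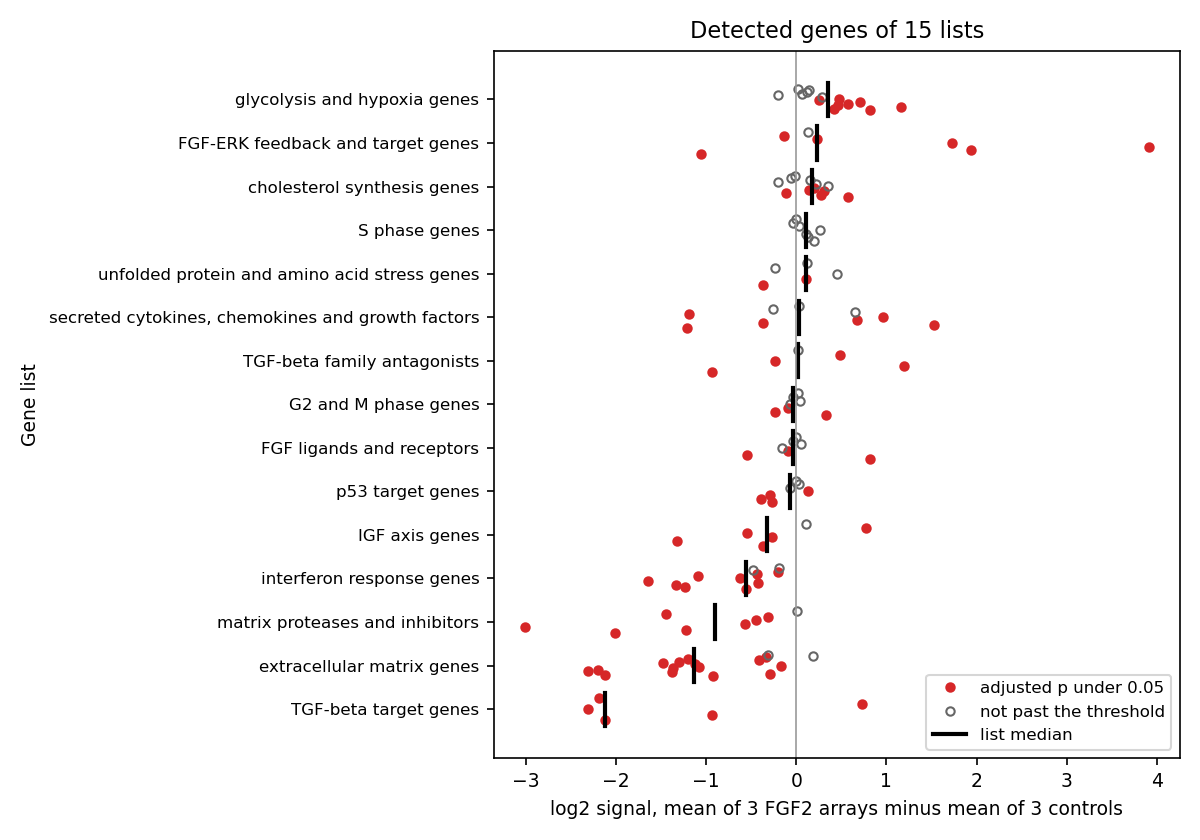
Log2 signal with FGF2 (mean of 3 arrays) minus control (mean of 3 arrays) for each detected gene of the 15 tested lists; filled red points passed at an adjusted p under 0.05, open points did not, and black bars are list medians. The medians range from -2.12 (TGF-beta target genes) to 0.35 (glycolysis and hypoxia genes).

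The second set of comparisons asked what each dose did against the 3 controls. Errfi1 was higher by 3.12 on the log2 scale at 4 ng/ml, 4.24 at 13 ng/ml and 4.36 at 40 ng/ml. Ptn had log2 changes of -3.57, -5.26 and -5.28 at these doses, and Socs2 of 0.95, 2.21 and 2.67. Matrix genes had list medians of -0.71, -1.36 and -1.33, and interferon response genes of -0.64, -0.51 and -0.52. At 4 ng/ml, 1633 probes passed in limma (860 higher and 773 lower). At 13 ng/ml the count was 3019 (1561 higher and 1458 lower), and at 40 ng/ml it was 2923 (1535 higher and 1388 lower). Over the probes called for all doses together, the median size of the log2 change was 0.286 at 4 ng/ml, 0.374 at 13 ng/ml and 0.374 at 40 ng/ml, and 78.8% of them changed less at 4 than at 40 ng/ml. Each dose has 1 array, so these counts rest on the spread of the controls, and without control replicate 1 they were 307, 1271 and 1243. At 4 ng/ml the count was 853 without control replicate 2, and at 40 ng/ml scaling to the same median gave 40.4% of called probes higher in place of 52.5%.

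The third comparison asked which genes changed in step with the dose among the treated arrays. For Socs2 the slope was 0.52 ± 0.06 per log2 of dose (adjusted p = 0.268) and for Serpina3g -0.98 ± 0.14 (adjusted p = 0.315). Spp1 had a slope of 0.00011 ± 0.017 (adjusted p = 0.999). In limma 0 of 11763 probes passed, and 1236 had an unadjusted p under 0.05. With 1 treated array left out the slope is the difference between 2 single arrays, with the spread taken from the controls alone. In that form 0 probes passed without the 4 ng/ml array, 90 without the 13 ng/ml array and 97 without the 40 ng/ml array.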

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

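The 2 settings of normexp without control probes, the restriction to probes with 1 leading zero and the trended prior in camera were chosen after the data had been seen; the other alternatives were planned. Among 16 alternatives other than the estimated correlation, the matrix, matrix protease, interferon and glycolysis lists passed in 16 each. Their medians ranged from -1.35 to -1.0, -1.03 to -0.51, -1.87 to -0.43 and 0.29 to 0.47. TGF-beta target genes passed in 12 of 15. With the correlation estimated from the data, 0 lists passed in camera in place of 5. In fry, which does not compare a list with other genes, 9 passed. Of the 101 genes picked by the naming rule, 85 passed. Of these 85, 67 kept their call with each array left out and 70 under each of 8 other processing alternatives, and 0 reversed. The rule picked them for large changes or small p in these same data, which favours keeping a call. Over all probes, 2569 of the 4327 calls were kept without the 40 ng/ml array and 2787 without control replicate 1. Of 91 picked genes in the authors' value table, 37 had a log2 change within 1 SD of the FGF2 arrays and 54 moved by more. Across 10381 probes the changes correlated at 0.877, and 99.97% of called probes had the same sign.

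The slope test passed 0 probes with the method fixed beforehand, 37 without further background correction, 49 and 5 with normexp at offsets of 50 and 16, and 71 with a trended robust prior. A rank trend that adds the controls as the lowest level passed 3437, and by its construction includes the difference between control and FGF2. At 4 ng/ml, against 1633 probes, 2629 passed without further background correction, 2682 and 2484 with normexp at offsets of 50 and 16, 2605 with a trended robust prior and 922 with scaling to the same median. The cause of these shifts was not tested. Leaving out 1 array gave 2598 to 4899 probes for all doses (lowest without 40 ng/ml, and 2848 without control replicate 1), 0 to 97 for the slope, 307 to 1387 at 4 ng/ml, 1271 to 2800 at 13 ng/ml and 1243 to 2762 at 40 ng/ml, each fit having fewer arrays. The lowest count at each dose came without control replicate 1.

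No paired analysis was possible because each dose has 1 array and no labels pair it with a control. The slide as a block was not run, since slides are not given in the sources used here. For the lists the prior was trended but not robust, since camera has no robust option, and 5 lists passed with it. Leaving out another dose changes nothing in the test of a single dose. Genes near the detection limit, such as Spred1 and Fgf13, are limited by signal over background.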

Other observations

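The genes and families in this paragraph were chosen after their values were seen. Genes detected on 1 side only were examined as a group. On the side of FGF2, the prolactin family gene Prl2c2 rose at least 1.55-fold, the leukocyte tetraspanin Cd53 at least 1.44-fold and the laminin receptor subunit Itga6 at least 1.28-fold, all detected on the 3 FGF2 arrays and on no control. On the side of the controls, the secreted serine protease Htra3 fell at least 1.52-fold, the prostaglandin-degrading enzyme Hpgd at least 1.26-fold, and the interferon-inducible genes Trim30a and Ifi27l2a at least 1.47-fold and 1.36-fold. Among 80 families formed from gene symbols and tested with camera, only the collagens passed, a family that overlaps the matrix list (Col, 9 of 11 fell and 0 rose, median -1.13, adjusted p = 0.000524, and an adjusted p = 0.808 with an estimated correlation). Regulatory subunits of the proteasome (Psmd) had 5 of 6 genes that rose, with a median of 0.32, but the family did not pass (adjusted p = 0.0861).

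Of the tests below, those on the 4 ng/ml array and the splits for probes were chosen after the result was seen. The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. For probes, 1 split gave as many calls as the real one, which was the real one itself with 4327, and the highest of the others gave 0. Every other split puts control and FGF2 arrays on the same side, so that their difference adds to the spread. Any strong grouping, a batch included, would give this outcome, and no conclusion is drawn from it. For lists, 2 splits gave as many, with 5 in the real one and 5 in the highest other (control replicate 1 with the 4 and 13 ng/ml arrays against the rest).

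The 4 ng/ml array lay between the controls and the higher doses on the first principal component, and control RNA mixed into a sample otherwise like the higher doses would bring every probe the same share of the way back to the control on the linear scale. Among called probes over 2-fold and detected on all arrays, the 193 raised reached a median of 57.1% of their change at the higher doses and the 251 lowered 86.6%. The difference was 29.6 points, and 22.9 to 33.1 points under the other background corrections and scalings, which argues against mixing as the whole cause. Permuted labels gave a range of -5.55 to 5.38 (permutation p = 1e-05, the smallest they can give). All probes were read from 1 array at 4 ng/ml and are not independent replicates. This p therefore measures scatter between probes, not between arrays or cultures. For a graded response to the dose, the slope test with 1 treated array left out, which then compares 2 single arrays, passed 0 probes without the 4 ng/ml array, 90 without the 13 ng/ml array and 97 without the 40 ng/ml array. With 1 array per dose, a graded response and a difference of this array cannot be told apart.

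Matrix genes fell together, with a list median of -1.13. The central 95% of 10000 random lists of like brightness had medians between -0.158 and 0.159, which argues against probe brightness as the whole cause. Scaling between arrays moved the list little, to a median of -1.14 with median scaling. In camera at the preset correlation, the list's adjusted p was 1.09e-05 with median scaling and 8.1e-07 with quantile normalisation. In camera with an estimated correlation, it was 0.463 with quantile normalisation. A response of matrix genes to FGF2 may account for the fall, as a hypothesis found and tested on the same arrays. A difference in hybridisation day between control and FGF2 arrays is untested.

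Interferon response genes also fell together, with a median of -0.559 against -0.101 to 0.104 in random lists of like brightness, which argues against brightness as the whole cause. Control replicate 3 had the highest mean over this list, though not the highest level of B2m or Irf1. Against control replicate 2 alone, which had the lowest mean of the controls, the list median was still -0.435. Interferon signalling itself was not measured, and a difference between the culture batches of control and treated cells is untested.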
